A study of Mus musculus with 3 samples.

How the data were processed

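RNA from Hopx-null embryoid bodies grown with XAV939 (12.5 µM) and from Hopx-heterozygous embryoid bodies, both at day 8 of cardiac differentiation, was compared directly on 3 two-colour Agilent arrays, which the labels call biological replicates. Per the file headers the arrays share probe design 026655, annotated on the mouse build mm9, and hold 44397 spots, 43020 of them not controls. Array 1 lay on one slide and arrays 2 and 3 on another.

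The spot and local background signals are deposited as median pixel intensity in each channel. The authors extracted them with Agilent Feature Extraction, whose version is 11.5.1.1 per the file headers and 8.5.1.1 in the submitters' notes. The deposited processed signals are also intensity values, background-subtracted and dye-normalized by Feature Extraction, and the deposited log ratio is log10 of Cy5 over Cy3. The authors' processed values are log2 ratios judging from their fit to the scanner ratios (slopes 0.688, 0.799 and -0.798 on log2 Cy5 over Cy3 of the median signals, r 0.885, 0.945 and -0.940). Their exact normalization and centring are stated nowhere in the sources used here (column medians 0.085, -0.08 and 0.053; 16, 15 and 3 values missing). Per the file headers the remaining columns used are 0 or 1 marks for spots that are saturated, outliers or well above background.

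The design assumed that the null RNA was in Cy5 on every array, as the labels state. The ratios of array 3 ran opposite to those of arrays 1 and 2, and the authors' values for array 3 have the sign of Cy3 over Cy5, so its ratio was turned; this was decided after the data were examined. The authors' columns correlate at 0.80, 0.729 and 0.835 with each other. The overall direction rests on the labels of arrays 1 and 2, the authors' values and Hopx, and stays likely rather than settled.

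The 39429 distinct probes were named through RefSeq accessions: 28025 had 1 symbol, 11404 had no match and 0 had several, which gave 21153 symbols. Median signals were corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 (R 4.3.3). Local backgrounds that Feature Extraction marks as outliers, which reached 65528, were replaced by the channel's median unmarked background, a choice made after the data were examined. A probe was tested if it was well above background in at least 1 channel on each of the 3 arrays, and each gene was taken from its brightest tested probe, which left 14710 genes. Of 3801 genes with several tested probes, 199 had probes called in opposite directions, Nanog among them. Of 5110 tested probes without a gene name, 1117 were higher and 1459 lower.

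A moderated t-test (limma) compared the mean log2 ratio with 0, with p-values adjusted over the 14710 genes by Benjamini and Hochberg and a threshold of 0.05. The moderated test had 8.66 degrees of freedom, 6.66 of them from the prior. These p-values measure the spread between the 3 arrays. The ratio is within each array, so each array is its own pair. On simulated ratios of 14710 genes (5 runs, 200 changed genes each) the test recovered 66.8% of changes of 2-fold and 91.6% of 4-fold, with 1.7% of calls false. The simulation changed far fewer genes than the 9486 that passed in the data, and drew noise independently for each gene. These rates therefore need not hold for the data. The number of arrays limits the precision: the median SD over the 3 arrays was 0.166 on the log2 scale, and the ratios correlated across genes at 0.971, 0.896 and 0.917.

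The share of probes well above background on arrays 1, 2 and 3 was 65.2%, 68.0% and 61.4% in Cy3 and 56.6%, 66.6% and 61.6% in Cy5. Negative controls in Cy5 had a median of 104 on array 1, against 46 and 48.5 on arrays 2 and 3. Saturated spots numbered 1, 34 and 32 in Cy3 and 57, 130 and 74 in Cy5.

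Before the data were examined, 23 gene lists with 662 entries were written from general knowledge, 659 of which are on the array, 3 under an updated symbol. They cover contractile, cardiac factor and calcium handling genes, Wnt targets, Wnt ligands, the destruction complex, BMP targets, BMP ligands, primitive streak, pluripotency, endoderm, endothelium, blood, smooth and skeletal muscle, neural, matrix, epicardium, cell cycle, stress, hypoxia, oxidative phosphorylation and sex-linked genes. Camera tested each list against the other genes with a preset correlation of 0.01, and with a correlation estimated from the residuals as an alternative. At the preset correlation 14 lists passed, and none of the 14 passed with the estimated one. For the cardiac factor, Wnt target, calcium handling, BMP target and BMP ligand lists the estimate was not above 0.01 (0.0099, -0.035, -0.0069, -0.0098 and -0.021). A higher correlation between genes therefore does not account for the higher p of these lists. With an estimated correlation camera tests on the 2 residual degrees of freedom of the 3 arrays, against many more with the preset one. It therefore has little power here. Fry, a rotation test of whether a list's own genes move in one direction, passed 13 of the 14 (not blood, adjusted p = 0.0564) and 4 lists that camera did not pass: Wnt ligands (adjusted p = 0.0167), epicardium (0.0094), primitive streak (0.0163) and sex-linked genes (0.0167). A list's shift is its mean log2 ratio minus that of the other genes. Counts adjusted over a list alone reuse the same p-values, so they are no separate support.

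The genes to name were also fixed before the data were examined. They are Hopx, the 12 largest changes in each direction among genes with a proper name, an adjusted p below 0.05, one sign on all arrays and a standard error under 50% of the mean, the up to 4 largest passing changes of each list, and Axin2, Lef1, Nkx2-5, Gata4, Isl1, Tnnt2, Myh6, Myl2, Myl7, T and Pou5f1. Not every gene that this rule picks is printed. Mixl1 was not tested because it was not well above background. List members named beyond this rule, to spell out counts of 5 or fewer, were chosen after their values were seen.

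Alternatives chosen before the data were examined changed the background correction (none, half-floored), the normalization (Feature Extraction log ratio, median centring, scaling between arrays, the authors' values), the filter (none, both channels), the probe summary (mean), the variance model (intensity trend and robust), the fit (separate channels), the replicates (each left out in turn) and the list test (estimated correlation, fry). Chosen after the data were examined were array 3 as labelled, marked local backgrounds kept, a gene-wise dye term, the slide as a fixed block and all tested probes. Median signals took the place of the planned mean signals, for which the files have no column. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.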

Results

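Gene expression was measured on 3 two-colour Agilent arrays, each of which set RNA from Hopx-null embryoid bodies grown with a Wnt inhibitor directly against RNA from Hopx-heterozygous embryoid bodies. Embryoid bodies are aggregates of differentiating embryonic stem cells, here from lines made from mouse blastocysts and taken at day 8 of a cardiac differentiation protocol. Hopx encodes a small homeodomain protein that does not bind DNA itself and is expressed in the developing heart. The inhibitor, XAV939 at 12.5 µM, blocks tankyrase, which stabilises axin and so lowers β-catenin. The 3 arrays are replicates 1 to 3 of a single comparison, and their number limits its precision. The share of probes well above background ranged from 61.4% to 68.0% in Cy3 and from 56.6% to 66.6% in Cy5.

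The comparison asks how gene expression in Hopx-null embryoid bodies with Wnt signalling inhibited differs from that in heterozygous ones. The null cultures with inhibitor had lower RNA levels of endoderm, heart muscle and BMP target genes. Levels were higher for pluripotency genes, cell cycle genes and a neural list whose largest rises include genes of the epiblast. These are list calls at a preset correlation between genes, and none of them passed with an estimated one (adjusted p = 0.277 for endoderm, contractile, BMP target and neural genes and adjusted p = 0.398 for pluripotency and cell cycle genes). With an estimated correlation the test has only 2 residual degrees of freedom and little power, so not passing it does not decide against a list. Of 14710 genes tested, 4636 were higher and 4850 lower in the null cultures with inhibitor at an adjusted p below 0.05 by limma, 1145 and 1406 of them by 1 or more on the log2 scale. The numbers of higher and lower members of a list given below are to be read against these shares of all genes. The sign on all 3 arrays was the same for 9401 of the 9486 genes. The counts were 2669 higher and 2260 lower with local backgrounds marked as outliers kept rather than replaced, and 3039 and 2023 with median centring in place of loess (60.0% higher against 48.9%). This direction is likely rather than settled. The labels put the null RNA in Cy5 on every array, but the Cy5 over Cy3 ratios of replicate 3 correlated at -0.71 and -0.77 across probes with those of replicates 1 and 2, which correlated at 0.83 with each other. Replicate 3 was therefore turned, as it is in the authors' processed values. The basis for the direction is the labels of replicates 1 and 2, the authors' values and the lower Hopx signal. If the overall direction were the opposite one, every sign given here would turn, with 4850 genes higher and 4636 lower and every list reversed. With replicate 3 used as labelled, limma called no gene (0 higher and 0 lower, with 13 and 27 at an unadjusted p below 0.05).

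Hopx, the targeted gene, was 6.54-fold lower in the null cultures, with a mean log2 ratio of -2.71 ± 0.05 (SD, n = 3 here and for all genes below; adjusted p = 2.03e-07). The replicates gave -2.65, -2.75 and -2.73. A second Hopx probe was 4.77-fold lower, at -2.25 ± 0.15. Whether either probe lies in the deleted part of the gene is not given in the sources used here. The Hopx signal stayed well above background in the null cultures on all 3 arrays. All genes said below to rise or fall passed the same test, Axin1 with the highest adjusted p of 0.0495, and had one sign on all 3 arrays except Dvl3 and Eno1. With local backgrounds marked as outliers kept, a choice examined after the data were seen, Actn3, Bmp5, Bnc1, Dvl3, Etv2, Myh3, Ryr2 and Smad9 were among those that did not pass.

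Of the 12 largest falls among genes with a proper name, 4 (Cubn, Rbp4, Foxa1 and Foxa2) belong to the endoderm list. Cubn, which encodes the endocytic receptor cubilin, was 46.4-fold lower (-5.54 ± 0.61), and Rbp4, the plasma retinol carrier, 36.4-fold lower (-5.18 ± 0.36). Srgn, the proteoglycan serglycin, fell by a similar amount (-5.45 ± 0.44). The forkhead factors Foxa1 (-4.33 ± 0.10) and Foxa2 (-4.27 ± 0.14), which specify endoderm, fell with them. The others were Igfbp1 (-5.04 ± 0.45), the water channel Aqp8 (-4.85 ± 0.07), the prostaglandin transporter Slco2a1 (-4.64 ± 0.14), B4galnt2 (-4.64 ± 0.31), Hkdc1 (-4.58 ± 0.38), the protease gene Ctsh (-4.41 ± 0.36) and Cyp2s1 (-4.29 ± 0.26).

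Among the 12 largest rises, Pou3f1 (4.46 ± 0.28), Fgf5 (3.99 ± 0.40) and the DNA methyltransferase gene Dnmt3b (3.83 ± 0.16) are expressed in the epiblast. Pou3f1 rose 22-fold and Fgf5 15.9-fold. Slc27a2, a fatty acid transporter and ligase, rose 28.5-fold (4.83 ± 0.39), and Calca, the calcitonin gene, 28.5-fold (4.83 ± 0.37). Pf4, the platelet chemokine (3.83 ± 0.73), and Myb, a transcription factor of blood progenitors (3.59 ± 0.24), also rose. The remaining ones were Slc45a1 (4.03 ± 0.05), the cationic amino acid transporter Slc7a3 (3.86 ± 0.42), Slc35d3 (3.66 ± 0.39), Magohb (3.54 ± 0.23) and the primase subunit gene Prim2 (3.53 ± 0.42). Adjusted p-values of these 24 genes ranged from 7.45e-08 to 1.66e-06.

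**Figure D1:**
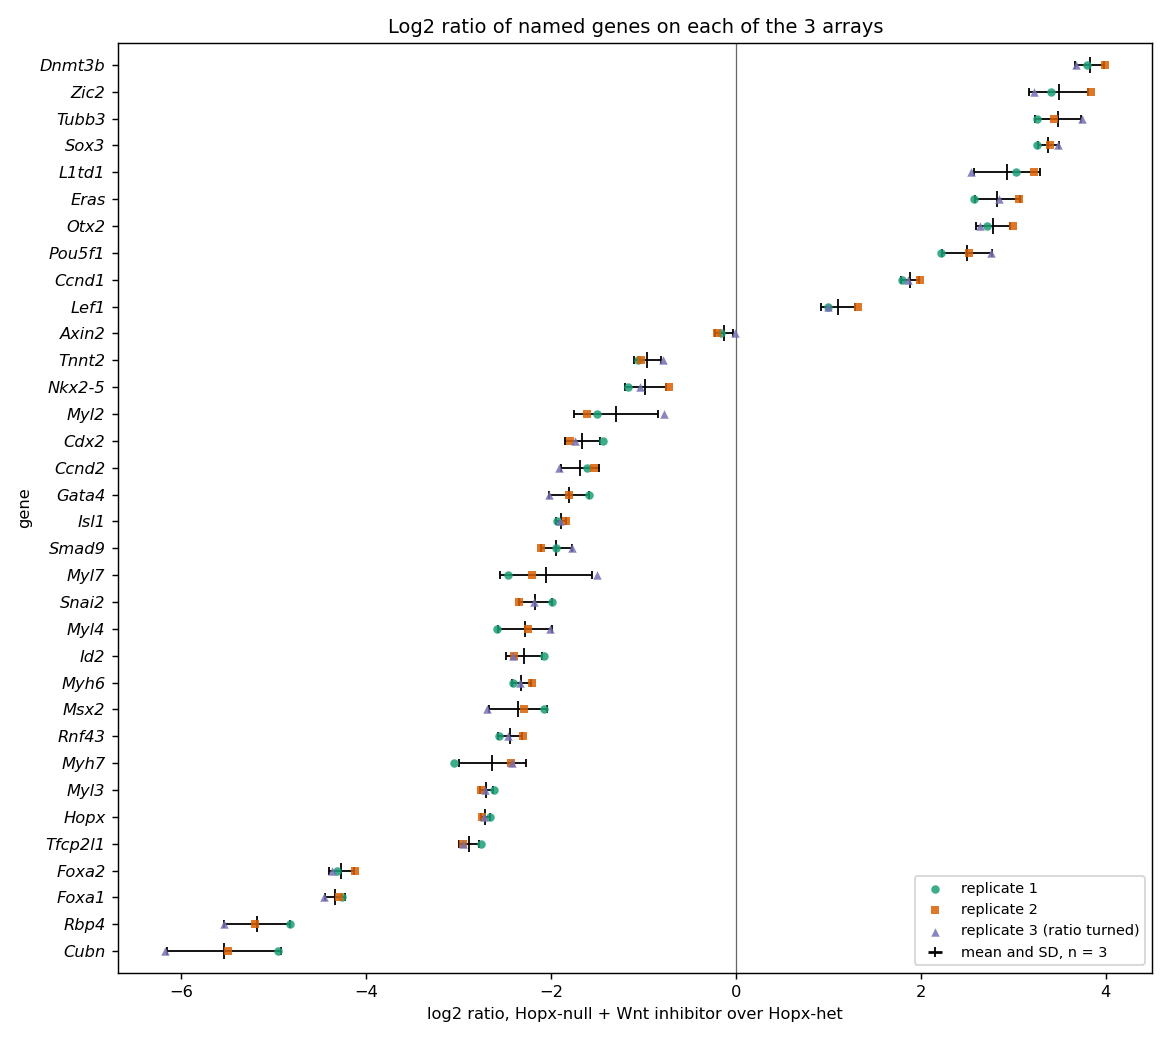
Log2 ratio of Hopx-null with Wnt inhibitor over Hopx-het (x axis) for 34 named genes (y axis). Coloured symbols are the 3 replicates, with the ratio of replicate 3 turned, and black marks give the mean and SD (n = 3); Cubn lies lowest at -5.54 and Dnmt3b highest at 3.83, and the 3 replicates of each gene lie on one side of 0.

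Genes of the contractile apparatus of heart muscle fell together. Of 25 tested members, 24 were lower and none higher, and Smyd1 (-0.27 ± 0.21) did not pass the test; adjusted over the list alone, all 25 were lower. The myosin light chain gene Myl3 was 6.49-fold lower (-2.70 ± 0.07), the heavy chain genes Myh7 and Myh6 6.2-fold (-2.63 ± 0.36) and 4.99-fold (-2.32 ± 0.10), and the atrial light chain gene Myl4 4.86-fold (-2.28 ± 0.29). Myl7, another atrial light chain, lay at -2.06 ± 0.50, the ventricular light chain Myl2 at -1.30 ± 0.45 and cardiac troponin T, Tnnt2, at -0.96 ± 0.14. The list lay -1.47 (log2) from the other genes (camera adjusted p = 8.21e-10 with a preset correlation, adjusted p = 0.277 with an estimated correlation).

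Cardiac transcription factors and progenitor genes fell as a list, with 19 of 27 tested members lower and 3 higher, the same counts as when adjusted over the list alone. Tbx3, a T-box factor of the conduction system, was 8.93-fold lower (-3.16 ± 0.24), and Pdgfra, a receptor of cardiac mesoderm, 5.62-fold (-2.49 ± 0.40). Tbx1 (-2.01 ± 0.20), Gata6 (-1.93 ± 0.32), Isl1 (-1.89 ± 0.05), which marks second heart field progenitors, Gata4 (-1.80 ± 0.22) and Nkx2-5 (-0.98 ± 0.23) fell as well. The 3 that rose were the early mesoderm factor Mesp1 (0.86 ± 0.18, well above background in the heterozygous cultures on 1 of 3 arrays) and the forkhead factors Foxc1 (0.93 ± 0.08) and Foxc2 (1.57 ± 0.17). Gata5 (-0.10 ± 0.05), Mef2c (0.11 ± 0.18), Tbx2 (0.10 ± 0.08), Irx3 (-0.14 ± 0.23) and Hey2 (-0.18 ± 0.18) did not pass. The list's shift was -0.84 (adjusted p = 0.000291, and adjusted p = 0.277 with an estimated correlation).

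Genes of calcium handling, conduction and heart hormones fell as a list, with 18 of 26 tested members lower and 6 higher, over all genes and adjusted over the list alone. Cox6a2, a muscle subunit of cytochrome c oxidase, was 11.1-fold lower (-3.47 ± 0.45), followed by the ryanodine receptor Ryr2 (-1.75 ± 0.29), the atrial natriuretic peptide gene Nppa (-1.52 ± 0.30) and Cox7a1 (-1.47 ± 0.33). The shift was -0.57 (adjusted p = 0.00646, and adjusted p = 0.277 with an estimated correlation), and it did not pass with probes well above background in both channels (-0.58, adjusted p = 0.0539, over alternatives from 0.000829 to 0.359). In the same cultures the endoderm list had a lower shift than the heart lists, a difference that was not tested, and the pluripotency and neural lists rose, as given below.

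Canonical Wnt targets moved in both directions, with more falling. Of 23 tested members 15 were lower and 3 higher, the same as when adjusted over the list alone. Rnf43, a ligase that removes Wnt receptors, was 5.42-fold lower (-2.44 ± 0.13), and Ccnd2 (-1.69 ± 0.20) and the caudal homeobox gene Cdx2 (-1.66 ± 0.19) also fell. The 3 that rose were the cyclin gene Ccnd1, 3.69-fold (1.88 ± 0.10), and the genes of the β-catenin partners Lef1 (1.11 ± 0.19) and Tcf7 (0.55 ± 0.15). Axin2, a feedback target, lay at -0.12 ± 0.10 (adjusted p = 0.305) and was well above background in the null cultures on 2 of 3 arrays. With the Feature Extraction log ratio Axin2 passed as lower (-0.48, adjusted p = 0.0119, over alternatives from 0.0119 to 0.995). Lgr5 (-0.12 ± 0.11), Cdx1 (-0.05 ± 0.13), Fzd7 (0.17 ± 0.14) and Myc (0.10 ± 0.14) did not pass either. T, which encodes brachyury, was not tested because its probe was not well above background on every array. The shift was -0.41 (adjusted p = 0.0186, and adjusted p = 0.277 with an estimated correlation), and the list did not pass with marked local backgrounds kept (-0.26, adjusted p = 0.0916, over alternatives from 0.00604 to 0.277).

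Wnt ligands, receptors and secreted antagonists did not pass camera as a list, at -0.09 (adjusted p = 0.435), but passed fry, which tests the list's own genes (adjusted p = 0.0167, over alternatives from 0.0167 to 0.662), and 9 of 34 tested members rose and 14 fell, also adjusted over the list alone. The secreted antagonists Sfrp1 (2.40 ± 0.19) and Sfrp2 (2.24 ± 0.21) and the ligand gene Wnt5b (2.03 ± 0.05) rose, and Wnt11, a ligand of heart development, fell (-2.24 ± 0.33). Of 18 destruction complex and tankyrase genes, 4 rose and 6 fell, or 3 and 6 adjusted over the list alone, and the list's shift was -0.035 (adjusted p = 0.765), or 0.015 with median centring (adjusted p = 0.986, over alternatives from 0.567 to 0.986). Those that rose were the ubiquitin ligase gene Btrc (1.47 ± 0.08), Tcf7l1 (0.72 ± 0.11), Apc2 (0.53 ± 0.22) and Axin1 (0.31 ± 0.25). Tcf7l2 fell (-1.17 ± 0.56). Dvl3 passed the test (-0.92 ± 0.91, adjusted p = 0.0148) with replicate 3 at 0.12, and did not pass without replicate 2 (-0.71, adjusted p = 0.0519, over alternatives from 1.32e-06 to 0.995). It also did not pass limma's test with the Feature Extraction log ratio (adjusted p = 0.0531), half-floored background (0.0596) or median centring (0.0531). Leaving out each replicate in turn gave Dvl3 ratios from -1.442 to -0.615.

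Targets of BMP signalling fell, with 16 of 17 tested members lower and none higher, also adjusted over the list alone. The homeobox gene Msx2 was 5.11-fold lower (-2.35 ± 0.31) and the inhibitor of differentiation Id2 4.91-fold (-2.29 ± 0.19). Snai2 (-2.17 ± 0.18) and the receptor-regulated Smad gene Smad9 (-1.94 ± 0.17) fell with them, while Dlx3 lay at 0.20 ± 0.19. The list's shift was -1.21 (adjusted p = 5.22e-06, and adjusted p = 0.277 with an estimated correlation). BMP ligands, receptors and antagonists fell as a list, with a shift of -0.54 (adjusted p = 0.00752, and adjusted p = 0.277 with an estimated correlation), with 15 of 25 lower and 3 higher, or 16 and 3 adjusted over the list alone. The ligand genes Bmp4 (-1.64 ± 0.49) and Bmp5 (-1.61 ± 0.36) and the antagonist gene Fst (-1.90 ± 0.23) were lower. Smad5 was higher (0.49 ± 0.29), as were the receptor gene Bmpr1b (at least 1.67-fold) and Chrdl1 (at least 1.31-fold), which were well above background in the heterozygous cultures on 0 of 3 arrays.

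Endoderm genes had the lowest shift of the 23 lists, with 29 of 31 tested members lower, over all genes and adjusted over the list alone, and a shift of -2.55 (adjusted p = 3.1e-12, and adjusted p = 0.277 with an estimated correlation). Cubn, Rbp4, Foxa1 and Foxa2 led it. The 2 that rose, Cdh1 (1.21 ± 0.25) and Epcam (0.82 ± 0.26), encode epithelial adhesion proteins that pluripotent cells also carry. Fibroblast and extracellular matrix genes fell, with 18 of 32 lower and 4 higher, also adjusted over the list alone. Col1a1, the α1 chain of type I collagen, was 7.01-fold lower (-2.81 ± 0.38), and Fbln1 (-2.25 ± 0.35), Postn (-2.14 ± 0.49) and fibronectin, Fn1 (-1.74 ± 0.45), fell with it. Thy1 (0.97 ± 0.06), Ccl2 (0.72 ± 0.13), Prrx1 (0.52 ± 0.16, well above background in the heterozygous cultures on 2 of 3 arrays) and Mfap5 (0.32 ± 0.26) rose. The shift was -0.61 (adjusted p = 0.00451, and adjusted p = 0.423 with an estimated correlation). Genes of hypoxia and glycolysis fell, with 21 of 29 lower and 2 higher, or 22 and 2 adjusted over the list alone. Ndrg1 was 8.48-fold lower (-3.08 ± 0.56), and the collagen prolyl hydroxylase genes P4ha1 (-2.56 ± 0.25) and P4ha2 (-2.53 ± 0.04) and the glucose transporter gene Slc2a3 (-1.74 ± 0.36) followed. The glycolytic enzyme genes Pkm (1.07 ± 0.18) and Eno1 (0.39 ± 0.40, higher on 2 of 3 arrays and saturated in the null cultures on 1) rose. The shift was -0.80 (adjusted p = 9.16e-05, and adjusted p = 0.277 with an estimated correlation).

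Pluripotency genes rose, with 20 of 26 tested members higher and 3 lower, also adjusted over the list alone. Dnmt3b, L1td1 (2.93 ± 0.35) and Eras (2.83 ± 0.25) rose most, and Pou5f1, the gene of Oct4, rose 5.65-fold (2.50 ± 0.27). The 3 that fell were Tfcp2l1 (-2.89 ± 0.11), Klf4 (-2.55 ± 0.10) and Zfp42 (-1.19 ± 0.23). Dppa5a (-0.22 ± 0.27), Prdm14 (0.13 ± 0.28) and Trim71 (-0.24 ± 0.13) did not pass. The shift was 0.98 (adjusted p = 0.00012, and adjusted p = 0.398 with an estimated correlation). Primitive streak and early mesendoderm genes held 11 that rose and 5 that fell of 16, also adjusted over the list alone. Fgf5, the Nodal antagonist gene Lefty1 (2.55 ± 0.29), Foxh1 (1.79 ± 0.28) and Nodal (1.25 ± 0.17) rose, and Tbx6 (-0.97 ± 0.03), Snai1 (-0.78 ± 0.08), Evx1 (-0.70 ± 0.18), Fgf8 (-0.64 ± 0.32) and Wnt3 (-0.45 ± 0.16) fell. This list's shift of 0.72 did not pass (adjusted p = 0.056), but it did without replicate 1 (0.78, adjusted p = 0.0196) and without replicate 2 (0.68, adjusted p = 0.0327), and by fry (adjusted p = 0.0163), over alternatives from 0.0163 to 0.621. By camera it also passed with the mean over probes (adjusted p = 0.0394), no background subtraction (0.0485), no filter (0.0323), separate channels (0.0447) and the slide as a block (0.0362). It did not pass with an estimated correlation (adjusted p = 0.398).

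Neural genes rose, with 18 of 29 tested members higher and 2 lower, or 19 and 2 adjusted over the list alone. The zinc finger gene Zic2 rose 11.2-fold (3.49 ± 0.32), the neuronal tubulin gene Tubb3 11.2-fold (3.48 ± 0.25) and Sox3 10.4-fold (3.38 ± 0.11). Otx2, a gene of epiblast and forebrain, rose as well (2.78 ± 0.19), and Crabp1 (-0.93 ± 0.12) and Ncam1 (-0.34 ± 0.21) fell. Zic2, Sox3 and Otx2 are also among the genes of the epiblast after implantation examined below, so their rise is not particular to neural cells. The shift was 1.21 (adjusted p = 1.23e-05, and adjusted p = 0.277 with an estimated correlation). Cell cycle genes rose, with 30 of 38 higher and none lower, also adjusted over the list alone. The replicative helicase genes Mcm3 (2.19 ± 0.26) and Mcm5 (1.84 ± 0.25), the cyclin gene Ccne1 (1.92 ± 0.22) and the ribonucleotide reductase gene Rrm2 (1.72 ± 0.19) rose most. The shift was 0.79 (adjusted p = 2.58e-07, and adjusted p = 0.398 with an estimated correlation). Tubb3, Mcm5, Sfrp1 and Plvap lie on chromosome 8, whose 775 tested genes had a median log2 ratio of 0.235, against -0.023 for genes on other chromosomes.

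Endothelial genes rose, with 16 of 28 tested members higher and 4 lower, or 17 and 4 adjusted over the list alone. Plvap, a protein of endothelial diaphragms (1.83 ± 0.17), and the transcription factor genes Etv2 (1.68 ± 0.26) and Fli1 (1.64 ± 0.26) were higher, and Sox7 (-1.57 ± 0.23), Flt1 (-1.20 ± 0.18), Adgrf5 (-0.69 ± 0.54) and Tek (-0.34 ± 0.28) were lower. The shift was 0.48 (adjusted p = 0.00473, and adjusted p = 0.491 with an estimated correlation). Blood genes rose, with 16 of 26 higher and 4 lower, also adjusted over the list alone. Pf4, Myb and Coro1a (2.07 ± 0.17) rose most, and the 4 that fell were the cytokine receptor gene Csf1r (-2.55 ± 0.25), Lcp1 (-1.58 ± 0.36), Runx1 (-1.42 ± 0.42) and Cd68 (-1.11 ± 0.07). The shift was 0.64 (adjusted p = 0.00473, and adjusted p = 0.491 with an estimated correlation), and the list did not pass fry (adjusted p = 0.0564, over alternatives from 0.000114 to 0.792).

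**Figure D2:**
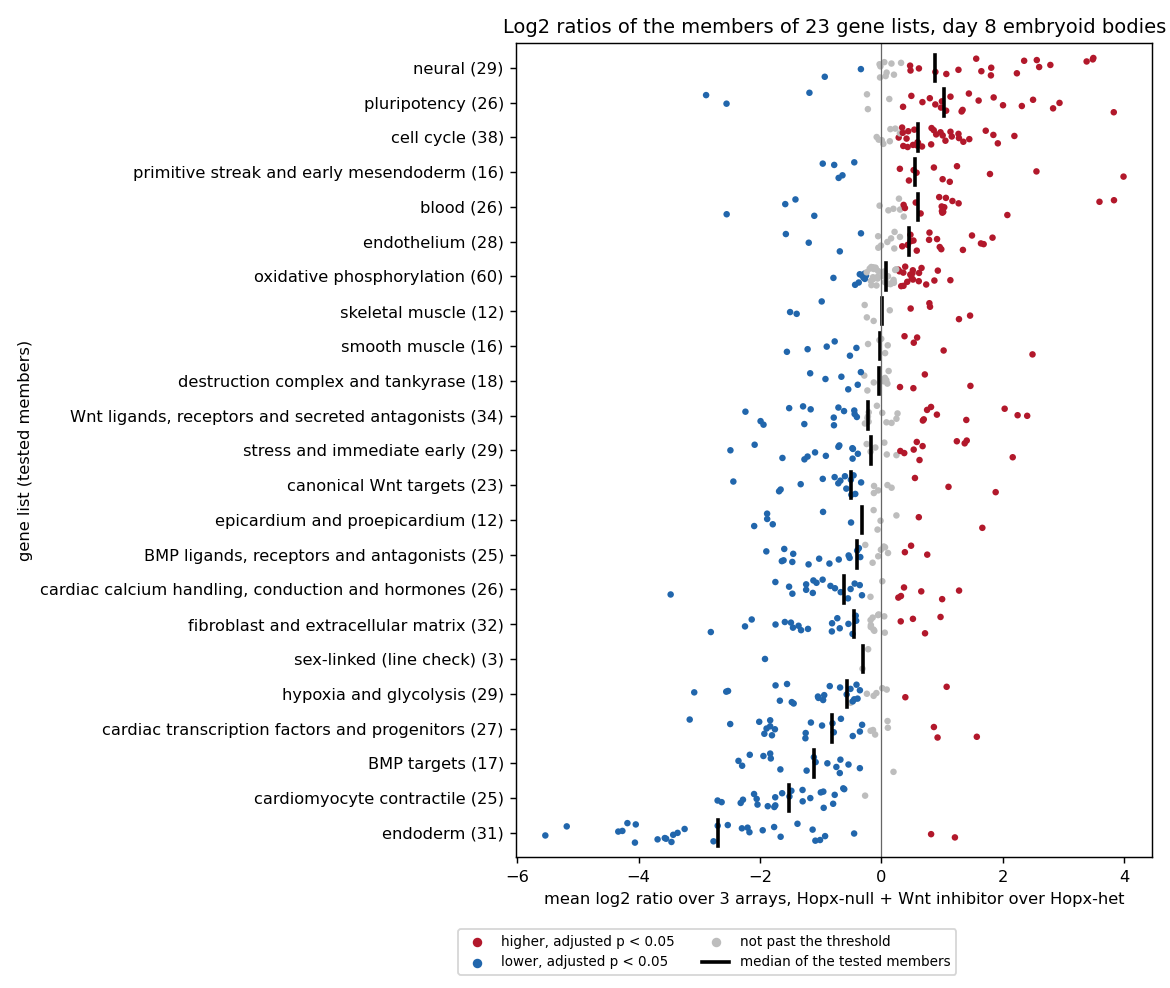
Mean log2 ratio over 3 arrays of Hopx-null with Wnt inhibitor over Hopx-het (x axis) for each tested member of 23 gene lists (y axis, number of tested members in brackets). Red and blue points passed limma's test as higher and lower, grey points did not, and black bars are list medians; the endoderm list lies lowest with a median of -2.70 and the pluripotency list has the highest median at 1.03.

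The remaining lists did not pass camera. Smooth muscle genes divided, with 5 higher and 6 lower of 16, also adjusted over the list alone. That is near the split of all tested genes (4636 higher and 4850 lower of 14710). The enteric actin gene Actg2 (2.49 ± 0.28) and Cnn1 (1.03 ± 0.25) rose with Tagln (0.59 ± 0.03), Pdlim3 (0.53 ± 0.15) and Tpm2 (0.38 ± 0.24), and Cald1 (-1.56 ± 0.16) and Des (-1.22 ± 0.31) fell. The list's shift of 0.0076 was positive while its median of -0.018 and mean of -0.028 were negative (adjusted p = 0.844). Of 12 skeletal muscle genes, Myh3 (1.46 ± 0.27), Actn3 (1.28 ± 0.28), Tnnc2 (0.80 ± 0.17), Tnnt1 (0.79 ± 0.15) and Pax3 (0.48 ± 0.17) rose and Myl1 (-1.50 ± 0.54), Myh8 (-1.40 ± 0.26) and Tnnt3 (-0.98 ± 0.23) fell, also adjusted over the list alone (shift 0.071 with adjusted p = 0.765, or -0.022 with median centring with adjusted p = 0.986, over alternatives from 0.389 to 0.991). Myh3 was well above background in the heterozygous cultures on 2 of 3 arrays. Of 12 epicardial genes 6 fell, among them Bnc1 (-2.10 ± 0.47), Upk1b (-1.88 ± 0.56), Podxl (-1.88 ± 0.12) and Krt7 (-1.79 ± 0.29), and Aldh1a2 (1.66 ± 0.56) and Scx (0.62 ± 0.06) rose, also adjusted over the list alone (shift -0.53, adjusted p = 0.161). The epicardial list did pass fry (adjusted p = 0.0094) and camera with median centring (-0.63, adjusted p = 0.0247), over alternatives from 0.0094 to 0.516. Bnc1 and Upk1b were well above background in the null cultures on 2 and 1 of 3 arrays. Of 29 stress and immediate early genes 10 rose and 13 fell, or 11 and 13 adjusted over the list alone (shift -0.13, adjusted p = 0.572). Gadd45b (-2.49 ± 0.14), Jun (-2.09 ± 0.53) and the cell cycle inhibitor gene Cdkn1a (-1.63 ± 0.09) fell and Chac1 (2.16 ± 0.45) rose. Of 60 oxidative phosphorylation genes 19 rose and 9 fell, or 17 and 5 adjusted over the list alone (shift 0.16, adjusted p = 0.196), and with median centring the list passed (0.34, adjusted p = 0.0031, over alternatives from 0.0031 to 0.857). Cytochrome c, Cycs (1.14 ± 0.21), Ndufs8 (0.93 ± 0.26) and Cyc1 (0.87 ± 0.17) rose and Ndufa6 fell (-0.79 ± 0.25), but did not pass with median centring (-0.54, adjusted p = 0.0707, over alternatives from 1.22e-05 to 0.995). Of 3 tested sex-linked genes, the Y-linked Eif2s3y was 3.78-fold lower (-1.92 ± 0.25), while Ddx3y lay at -0.31 ± 0.30 and Uty, well above background in the null cultures on 0 of 3 arrays, at -0.22 ± 0.08, also adjusted over the list alone (shift -0.78, adjusted p = 0.149). The sex-linked list passed fry (adjusted p = 0.0167, over alternatives from 0.0167 to 0.567).

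Replicates 2 and 3 shared a slide, and within it 3889 genes were higher and 4143 lower, against 4227 and 4407 with the slide as a block. Within that slide and with the block, Hopx lay at -2.74 and -2.69, the contractile list at -1.43 and -1.49, the cardiac factor list at -0.87 and -0.82, and the Wnt target list at -0.42 and -0.40. Genotype, inhibitor and stem cell line differed together on every array, so their effects cannot be told apart.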

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

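The tests with array 3 as labelled, marked local backgrounds kept, a dye term, a fixed slide block and all tested probes were chosen after the results were seen. The planned random slide block was not run, since 3 arrays on 2 slides gave no estimate of its correlation. The counts of 4636 genes higher and 4850 lower became 3039 and 2023 with median centring, 2669 and 2260 with marked local backgrounds kept (the cause was not tested for either), and 7005 and 7662 with all tested probes, where more probes than genes are tested. Median centring moved the median of all genes from -0.0109 to 0.096. With array 3 as labelled, opposed ratios cancel: limma called 0 higher and 0 lower (13 and 27 at an unadjusted p below 0.05), and 114 of 115 named genes and 8 lists lost significance. Hopx then lay at -0.891 (adjusted p = 0.995, over its alternatives 4.29e-10 to 0.995).

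The cardiac factor list lay at -0.268 with array 3 as labelled (adjusted p = 0.0633) and the Wnt target list at -0.106 (adjusted p = 0.247), or -0.260 with marked backgrounds kept (adjusted p = 0.0916). With the estimated correlation the contractile (-1.473), cardiac factor (-0.840) and Wnt target (-0.406) lists each had an adjusted p of 0.277. The shifts are those of the preset test. The estimated correlations were 0.056, 0.0099 and -0.035, against the preset 0.01. For the cardiac factor and Wnt target lists these values argue against a higher correlation between genes as the cause of the higher p. The test with an estimated correlation rests on the 2 residual degrees of freedom of the 3 arrays, which the preset test does not. For the cardiac factor list, at nearly equal correlations, the unadjusted camera p went from 0.000101 to 0.06005. Failure of the test with an estimated correlation therefore says little against these lists. Over alternatives the adjusted p ranged from 5.07e-13 to 0.277, 2.42e-05 to 0.277 and 0.00604 to 0.277.

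Lists near 0 that passed neither camera nor fry for a direction changed sign, and the cause was not tested: destruction complex (0.015 with median centring, 0.005 with marked backgrounds kept), smooth muscle (-0.003 with the filter on both channels, -0.007 with a dye term) and skeletal muscle (-0.022 with median centring, -0.046 with both channels, -0.098 with array 3 as labelled). Leaving out each replicate gave ranges of -0.083 to 0.007, -0.010 to 0.036 and -0.021 to 0.148 for these, and of 3505 to 5279 genes higher, 3712 to 5340 lower, -2.737 to -2.690 for Hopx, -1.513 to -1.430, -0.870 to -0.819 and -0.417 to -0.383 for the contractile, cardiac factor and Wnt target lists.

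Marked backgrounds kept also left, among others, Actn3 (0.724), Bmp5 (-0.774), Bnc1 (-0.971), Dvl3 (-0.739), Etv2 (0.977), Myh3 (0.705), Ryr2 (-1.094) and Smad9 (-0.986) short of the threshold. Signal over background limits which genes were tested, 14710 of 21153.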

Other observations

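The tests on array 3, on pluripotency genes and on sign splits were chosen after the results were seen. The 3 predictions on chromosome 8 were written before their tests were run. That chromosome was itself picked from these same data, as the one with the highest difference of medians. Besides Eif2s3y, Y-linked Sly (-0.996 ± 0.68, SD, n = 3) and Rbmy (-0.61 ± 0.21) were lower on all 3 arrays, and 6 of 8 tested genes on that chromosome passed as lower (adjusted p = 0.00287 for Sly and 0.00136 for Rbmy), but as a group they did not pass (difference of medians -0.503, adjusted p = 0.206, lower on 3 of 3 arrays). Of 10 tested neighbours of Hopx, Tecrl, a gene of the heart's endoplasmic reticulum, was lower (-1.59 ± 0.10), as were Aasdh (-0.67) and Srp72 (-0.65), while Noa1 (1.01), Ppat (0.81), Polr2b (0.74) and Spink2 (0.34) were higher and Paics (0.21), Rest (0.04) and Arl9 (-0.09) did not pass. Genes on chromosomes 14 and 3 lay lower as groups, by a difference of medians of -0.15 (adjusted p = 0.0011, same sign on 3 of 3 arrays) and -0.08 (adjusted p = 0.0182, 3 of 3 arrays).

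Array 3 ran opposite to arrays 1 and 2. Its Cy5 over Cy3 ratios correlated at -0.914 across genes with the mean of arrays 1 and 2, a size that argues against noise on array 3. Hopx was at 2.73 in Cy5 over Cy3 on array 3, against -2.65 and -2.75 on arrays 1 and 2. That would argue against an opposite response of the cultures only if genotype alone set the Hopx signal. The signal stayed well above background in the null cultures, and whether the probes lie in the deleted part is not given. An opposite response therefore stays open. An exchange of the RNAs or of the dyes on array 3 stays open, and the -0.914 does not bear on it, because it restates the pattern. No measured value separates an exchange of dyes from one of RNAs.

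Genes on chromosome 8 were higher as a group, with a difference of medians of 0.258 (0.254, 0.249 and 0.262 per array; 371 genes higher and 154 lower; adjusted p = 0.0011, from the smallest p that the draws can give). Signal intensity is argued against by random sets of the same size and signal, none of which had as high a median (permutation p = 0.0001, the smallest that 10000 draws can give; highest 0.086), while a part played by strongly changed genes stays open, since the difference of 0.142 in the 614 genes changed by less than 1 comes from a filter on the change itself and a median hardly responds to a few genes. An extra chromosome 8 in the null line may account for it, since all 4 stretches of the chromosome were higher, the lowest by 0.149 and the others by 0.286, 0.242 and 0.346. A full gain of 1 copy on 2 would give 0.58, a ratio cannot tell a gain in one line from a loss in the other, and karyotypes were not analysed here. Over the 18 alternatives the difference ranged from 0.083 without a filter to 0.356 with the Feature Extraction log ratio, and was 0.084 with array 3 as labelled.

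Pluripotency genes were higher as a list by camera at the preset correlation, but did not pass with an estimated one (adjusted p = 0.398). Of 14 genes of naive stem cells 7 were higher and 6 lower, with a median of 0.243. Nr0b1 (1.60), Tcl1 (1.14), Dppa3 (1.07), Nanog (0.996), Esrrb (0.98), Klf2 (0.89) and Fbxo15 (0.36) rose, though the tested probes of Nanog were called in opposite directions. Tbx3 (-3.16), Tfcp2l1 (-2.89), Klf4 (-2.55), Nr5a2 (-1.79), Klf5 (-1.46) and Zfp42 (-1.19) fell. Endoderm and other cells also express some of the genes that fell, so naive cells left in the cultures stay open. Of 14 genes of the epiblast after implantation 12 were higher, led by Pou3f1 (4.46; log2 levels 13.04 null and 8.58 het), Fgf5 (3.99; log2 levels 12.24 null and 8.25 het) and Dnmt3b (3.83; log2 levels 15.73 null and 11.90 het), and Cdh2 was lower (-0.51), with a median 2.26 above that of naive genes (permutation p = 0.00078). Cells like this epiblast may be more frequent in the null cultures. The permutation test cannot decide this, because it was chosen after the results were seen. Of the 14 epiblast genes, 7 were already picked by the naming rule, Lef1 by a part of it that did not use its value. The other 7 had a median of 1.24, against 0.622 for the 12 naive genes that the rule did not pick, and this difference was not tested. Those 12 include Klf4, Zfp42 and Prdm14, whose values are also given above. Neural cells express several of the epiblast genes too, and which cells carry the RNA was not tested.

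The 3 arrays allow 4 splits of their signs, too few for a share under 0.05. The split with array 3 turned gave 9486 genes by limma and the highest of the others, which include array 3 as labelled, 0. This leaves 1 of 4 with as many. Array 3 was turned after its opposite ratios were seen, which favoured that split, so no conclusion is drawn from the difference.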
